A study of Danio rerio with 6 samples.

How the data were processed

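RNA was measured in 6 pools of dissected larval zebrafish hearts, 3 labelled mutant and 3 from wild-type siblings. Per the labels' protocols, total RNA was extracted with the Qiagen miRNeasy kit, 6.5 ng entered the Clontech Pico Input Mammalian library preparation, and libraries were sequenced as single reads of 75 nt on a NextSeq500, with at least 30 M (megareads) each. A total RNA preparation of this kind keeps ribosomal and other structural RNA that is not removed, which lowers the depth left for messenger RNA. Per the submitters' processing notes, the tools were STAR 2.4.0a and featureCounts 1.4.5-p1 from Subread, with the danRer10 (GRCz10) assembly. The counting options, strand use included, are not given in the sources used here.

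The authors' table holds 1 value per gene and library, as whole numbers. These deposited values are a score, namely read counts scaled between libraries and rounded, and not raw counts. This was read from the values. In mutant replicates 2 and 3 and WT replicate 2, 7, 5 and 12 of the whole numbers from 1 to 100 never occur, as happens when counts are multiplied by a factor above 1 and rounded. Factors of 1.07, 1.05 and 1.13 predict exactly those gaps, and factors of 0.959, 0.880 and 0.895 fit mutant replicate 1 and WT replicates 1 and 3, where some whole numbers stand for several counts instead. Dividing the totals by these factors gives about 21.96, 20.28 and 20.87 M assigned reads in mutant and 21.81, 22.23 and 23.82 M in WT replicates 1 to 3. Because rounding merged neighbouring counts in 3 libraries, whole reads were not recovered, and the count models planned for raw counts were not run. The scaling method is not given in the sources used here. Each gene's symbol, Ensembl identifier and position are those of the table, and 26237 of its 31701 identifiers were also found in the gene name table used here.

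Values were analysed as log2(value + 1), so fold changes are on that scale and understate the change of low genes. Genes with a value of at least 10 in at least 3 of the 6 libraries were tested, 18901 in all, and 2277 genes stood at 0 in every library. The 3 mutant libraries were compared with the 3 WT libraries by limma 3.58.1 in R 4.3.3, with a mean-dependent variance trend and Benjamini-Hochberg adjustment over all genes tested; an adjusted p under 0.05 is a call. The series' design text describes the replicates as biological, each a pool of 23 hearts. The labels number the replicates of both genotypes from 1 to 3, and the numbers were not used to pair them.

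Gene lists for 35 pathways, cell types and complexes were fixed from textbook knowledge before the data were examined, including blood, liver and yolk, muscle, skin, cartilage and neuronal markers that a dissected heart could carry. Each list was tested against all other genes by camera, with a preset inter-gene correlation of 0.01 and with an estimated one, and on its own by fry, which tests whether its members move one way, with adjustment over the 35 lists. Members were also adjusted over their list alone. A list's score in a library is the mean log2 deviation of its tested members from their mean over the 6 libraries. Lists share few genes; the largest overlap is the 3 genes that the valve and matrix lists share.

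The genes named in the text follow a rule fixed with the lists. It takes *wwtr1* and *yap1*, then up to 12 genes that rose and 12 that fell with an adjusted p under 0.05, a mean value of at least 50, groups that do not overlap and a symbol that is not a clone name. It adds from each list up to 4 members that passed over all genes or, where fewer than 2 passed, up to 2 with the highest mean. Only 7 genes passed, so members that changed when adjusted over their list alone are also named. In the liver and yolk, immediate early and mitochondrially encoded lists only some of them are. These members, the genes with an unadjusted p only, and any others named beyond the rule were chosen after their values were seen.

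The scripts were tested on simulated data for the 18901 genes of this comparison, with 200 genes of a mean of at least 50 changed by known folds. The spread of a simulated gene followed a smooth trend with its mean, without a spread of its own. At 1.5-fold, 50% of 50 changed genes were recovered, at 2-fold 92%, and at 3-fold and 4-fold 100%. In that run 6 unchanged genes were called, 3.39% of the calls, and 0 genes were called when none was changed. A simulated list changed by 1.2-fold was recovered by camera with the preset correlation, with 0 other lists called. Genes were drawn independently of each other, so the simulation cannot show how often this test calls lists whose members are correlated.

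The alternatives were other pseudocounts and value filters, TMM factors (own implementation) and quantile normalisation, library weights, a replicate block, each library left out in turn, a stricter threshold, a minimum fold change, and the chromosome of *wwtr1* left out. Robust variance moderation, precision weights and a rescaling without the 20 most abundant features were added after seeing the data, as were the KEGG terms of the table's own annotation. No sequence-level analysis was made, since no genome was used here.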

Results

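Whole hearts were dissected by hand from zebrafish larvae at 57 to 59 hours post fertilization, from animals labelled mutant and from their wild-type (WT) siblings. The title of the series names Wwtr1, also called Taz, a transcriptional coactivator that acts at the end of the Hippo kinase pathway together with its relative Yap1. Each genotype had 3 biological replicates, each a pool of 23 hearts, and each gave 1 RNA sequencing library. The deposited values are normalised read counts per gene, rounded to whole numbers, and are reported in that unit throughout. They summed to 19187058, 25227868 and 21315482 in WT replicates 1 to 3 and to 21068538, 21682506 and 21968397 in mutant replicates 1 to 3. Features annotated as ribosomal RNA took between 40.4% and 43.9% of each total. Of 31701 genes in the table, 18901 reached a value of 10 in at least 3 of the 6 libraries and were tested. Coordinates are on the GRCz10 assembly.

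The single comparison in the design asks which cardiac transcripts differ between mutant hearts and WT sibling hearts. Transcripts of *wwtr1* itself were 3.30-fold lower in mutant hearts, at 126 ± 25.5 (SD, n = 3) against 416 ± 54.5 (n = 3), and the lowest WT library stood at 362 against 151 in the highest mutant library. Its log2 change was −1.72 with a standard error (SE) of 0.155 (limma, Benjamini-Hochberg adjusted p = 0.000251). The gene (ENSDARG00000067719) lies on the plus strand of chromosome 22, from 38095983 to 38161452. The paralogue *yap1* (ENSDARG00000068401, chromosome 18, 37302757 to 37374658) stood at 1302 ± 27.7 in mutant and 1246 ± 57.7 in WT hearts, a log2 difference of 0.06 that did not pass the test (SE 0.0821, adjusted p = 0.949).

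Beyond *wwtr1*, 2 genes rose and 4 fell in mutant hearts. The larger rise was in *cilp* (ENSDARG00000053362, chromosome 7, 31160990 to 31170270), which encodes an extracellular matrix protein first described in cartilage. It reached 1551 ± 78.0 against 775 ± 74.8, a log2 change of 1.00 (SE 0.0929, adjusted p = 0.000251). The intestinal-type alkaline phosphatase gene *alpi.1* (ENSDARG00000015273) rose from 311 ± 14.2 to 579 ± 18.0, a log2 change of 0.90 (SE 0.0973, adjusted p = 0.00128). This gene lies on chromosome 22 from 38776068 to 38791288, 0.655 Mb from *wwtr1*, and an antisense gene, si:ch211-262h13.7, overlaps it, so the reads of the pair may be mixed.

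The 4 other genes that fell were a growth factor, a Wnt receptor, an actin-binding regulator and a pleckstrin-domain protein. *BMP10* (ENSDARG00000045632, chromosome 10, 561903 to 567303), named in capitals in the annotation, encodes a secreted bone morphogenetic protein known for its part in the growth of the trabeculated ventricle. It stood at 111 ± 16.4 in mutant and 234 ± 22.5 in WT hearts, a log2 change of −1.07 (SE 0.149, adjusted p = 0.0123). The Frizzled receptor gene *fzd5* (ENSDARG00000025420, chromosome 9, 28421776 to 28423698) fell from 198 ± 24.2 to 92.0 ± 9.0, a log2 change of −1.09 (SE 0.152, adjusted p = 0.0123). *abraa* (ENSDARG00000038583, chromosome 6, 52064305 to 52072830), known from striated muscle, fell from 106 ± 10.2 to 38.3 ± 11.2, with a log2 change of −1.49 (SE 0.237) and an adjusted p of 0.0469. *phlda2* (ENSDARG00000042874, chromosome 25, 23427248 to 23428538) fell from 640 ± 45.7 to 374 ± 8.72, a log2 change of −0.77 (SE 0.0971, adjusted p = 0.00579).

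**Figure D1:**
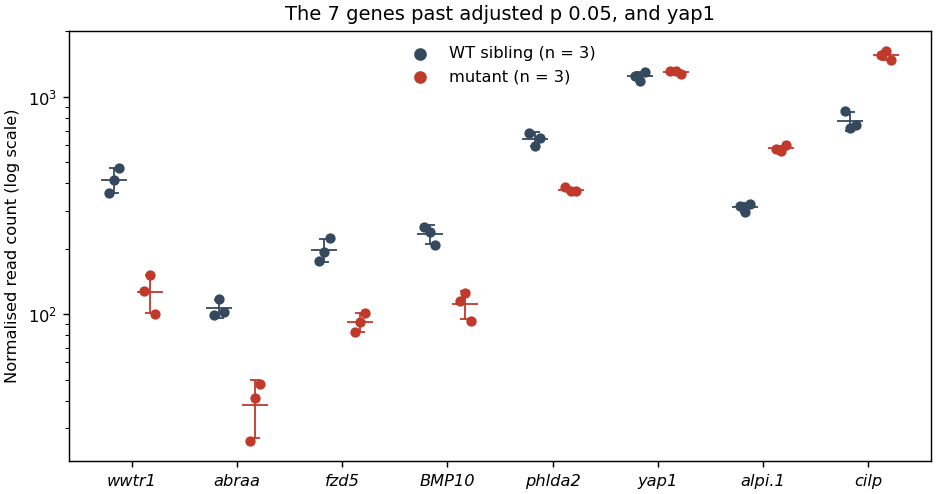
Normalised read count (log axis) of the 7 genes past an adjusted p of 0.05 and of *yap1*, in 3 WT sibling libraries (dark) and 3 mutant libraries (red); points are single libraries, and bars give the mean and SD. The mutant and WT points of each called gene do not overlap, with *wwtr1* at 100 to 151 in mutant and 362 to 471 in WT libraries, while those of *yap1* lie between 1186 and 1319.

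In all, 7 of the 18901 genes passed, 2 higher and 5 lower in mutant hearts. An unadjusted p under 0.05 was seen for 1248 genes, where 945 would be expected with no difference. The other splits of the 6 libraries into 3 and 3 gave 645 to 1139 such genes. Groups did not overlap in 11.1% of the tested genes, against the 10% that chance gives for 3 against 3. The count depended on single libraries. Without WT replicate 2, 32 genes were higher and 11 lower, among them all 7 above, and without WT replicate 1, 4 were higher. The 32 include *he1a*, *he1b* and *ctslb*, which were highest in WT replicate 2 among WT hearts. Whether the 32 are separate signals was not tested. Without mutant replicate 1, mutant replicate 2 or WT replicate 3, 3 were lower: the adjusted p of *fzd5* then reached 0.0777, 0.0770 and 0.120, that of *abraa* 0.0978, 0.121 and 0.213, and that of *BMP10* 0.0656 without mutant replicate 1. *BMP10* also missed the threshold without mutant replicate 3 (0.0618) and without WT replicate 1 (0.0678), where *abraa* reached 0.104.

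Of the 7 called genes, 2 lie on chromosome 22, which holds 686 of the tested genes (Fisher's exact test, p = 0.0245). With *wwtr1* left out, 1 of 6 called genes lies there (Fisher's exact test, p = 0.199). The plot of changes along this chromosome shows 112 tested genes other than *wwtr1* within 10 Mb of it, of which 19 had an unadjusted p under 0.05, or 17%, against 6.49% on the other chromosomes.

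**Figure D2:**
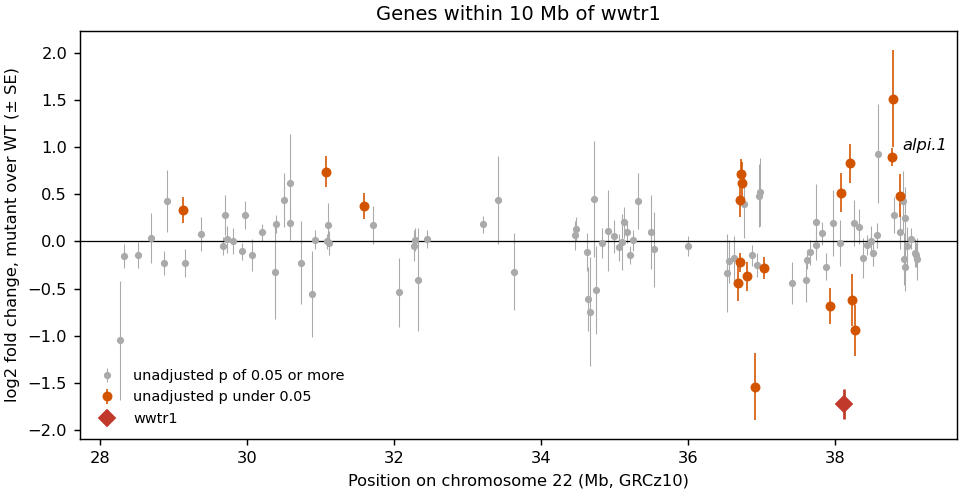
Log2 change between mutant and WT hearts, with its standard error, for each tested gene within 10 Mb of *wwtr1*, by its position on chromosome 22 in Mb; orange points have an unadjusted p under 0.05 and the red diamond is *wwtr1*. Of the 19 orange points, 11 lie above 0 and 8 below it, and 8 of the 19 lie within 1 Mb of *wwtr1*.

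Groups of genes fixed before the data were examined were tested next, 35 lists in all. Against the other genes, 8 lists stood higher and 8 lower in mutant hearts by camera with a preset inter-gene correlation of 0.01. None of the 16 held by camera with a correlation estimated from the data (lowest adjusted p = 0.446). There, 3 of 35 lists had an unadjusted p under 0.05. By fry, which tests each list on its own, none held for members moving 1 way (lowest adjusted p = 0.381). With this test 3 lists had an unadjusted p under 0.05. Fry for members moving either way was not adjusted over the lists. Its lowest unadjusted p were 3.29e-05 for the extracellular matrix, 8.69e-05 for the Wnt and 0.000144 for the BMP and TGF-beta genes. Single genes beyond those described above did not pass over all genes tested. Changes within lists are therefore given with the count adjusted over the list alone, which does not correct for the number of lists.

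Genes of the atrioventricular canal and valve were higher in mutant hearts. Of 22 measured members, 19 had a log2 change above 0 and 9 had every mutant value above every WT value; the median log2 change was 0.14 (camera adjusted p = 1.07e-06, and adjusted p = 0.446 with an estimated correlation). None passed over all genes tested, and 5 rose when adjusted over the list alone. These were *vcana* and *has2*, which encode the matrix proteoglycan versican and the enzyme that makes hyaluronan in the cardiac jelly, *twist1b* and *nfatc1*, transcription factors known from valve-forming cells, and *spp1*, the secreted phosphoprotein osteopontin. *vcana* stood at 2553 ± 248 against 1670 ± 202, a log2 change of 0.61 (SE 0.102, adjusted p = 0.0576 over all genes). *has2* stood at 941 ± 51.8 against 696 ± 57.9, a log2 change of 0.44 (SE 0.0938). The most abundant members, *notch1b* (6408 ± 310 against 5820 ± 222) and *alcama* (2768 ± 55.2 against 2374 ± 191), did not pass on their own. The call held with each library left out in turn, with a highest adjusted p of 0.000222.

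The 32 genes of the endocardium and endothelium had a median log2 change of 0.07 (camera adjusted p = 0.0189; adjusted p = 0.455 with an estimated correlation), and none passed alone. The vascular cadherin gene *cdh5* stood at 5571 ± 384 against 4492 ± 555 and the receptor gene *tie1* at 2183 ± 140 against 1806 ± 86.9. The call ended without mutant replicate 2 (0.0521), mutant replicate 3 (0.199) or WT replicate 2 (0.183). The list's mean difference of 0.08 went to 0.01 without mutant replicate 3 and to 0.04 without WT replicate 2, and it went to 0.12 without mutant replicate 1 (adjusted p = 0.00131) or WT replicate 3 (0.0234). The 52 extracellular matrix genes had a median log2 change of 0.08 (camera adjusted p = 0.0491; adjusted p = 0.455 with an estimated correlation). Adjusted over the list alone, 4 of them rose and 1 fell. Those that rose were *vcana* and *has2* again and the fibrillar collagen genes *col5a2a* (3783 ± 308 against 2742 ± 139) and *col5a1* (5080 ± 87.9 against 3944 ± 242), and the one that fell was the versican-cleaving protease gene *adamts9* (347 ± 49.5 against 519 ± 51.5). The most abundant members, *col1a1a* (6952 ± 160 against 5890 ± 948) and *col1a1b* (7488 ± 393 against 6412 ± 988), did not pass. The matrix call ended without mutant replicate 1 (0.0545), mutant replicate 2 (0.083), mutant replicate 3 (0.112), WT replicate 1 (0.136) or WT replicate 2 (0.227), and also with a minimum value of 50 (0.0995), with TMM factors (0.0518) and without the 20 most abundant features (0.0672). The list's mean difference of 0.06 went to 0.04 without WT replicate 2 and to 0.09 without WT replicate 3 (adjusted p = 0.00322).

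Epicardial and mesenchymal genes were lower. The 19 members had a median log2 change of −0.11 (camera adjusted p = 0.0138; adjusted p = 0.455 with an estimated correlation), and 2 fell when adjusted over the list alone. These were *tcf21*, a transcription factor of the epicardium (43.0 ± 13.1 against 91.7 ± 14.5, a log2 change of −1.11, SE 0.242), and *podxl*, which encodes the surface sialomucin podocalyxin (2018 ± 75.3 against 2514 ± 284). The matricellular gene *postnb*, the other abundant member, stood at 2661 ± 134 against 2377 ± 263. Without WT replicate 3 the list's mean difference went from −0.17 to −0.09 and its adjusted p was 0.109.

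Genes of the contractile myocardium did not pass as groups. The 46 sarcomere genes had a median log2 change of −0.01 and a mean of 0.02 (camera adjusted p = 0.632), with titin *ttn.2* at 144100 ± 13450 against 143300 ± 10150 and the ventricular myosin gene *vmhcl* at 102300 ± 4267 against 105800 ± 13100. The list passed, upward, without WT replicate 1 (0.0102). The 11 ventricular genes had a median of −0.04 (adjusted p = 0.676). Adjusted over that list alone, the transcription factor gene *irx3a* rose (572 ± 48.0 against 442 ± 46.0). The transcription factor gene *hey2* fell by the same adjustment (83.7 ± 13.6 against 127 ± 11). In the Notch list, which also holds *hey2*, its limma p adjusted over the list alone was 0.0588. The myosin gene *vmhc* stood at 60520 ± 5684 against 65190 ± 5747. The 11 atrial genes had a median of 0.01 and a mean of −0.03 (adjusted p = 0.342, tested downward), and *mybphb*, a myosin-binding protein gene, fell when adjusted over the list alone (1191 ± 94.0 against 1717 ± 190, a log2 change of −0.52). The most abundant members of the atrial list, *myh6* (30320 ± 1126 against 28000 ± 1611) and *nppa* (12280 ± 269 against 11890 ± 740), did not pass.

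The 28 genes of calcium handling and ion channels had a median log2 change of 0.04 (camera adjusted p = 0.137), and 1 rose when adjusted over the list alone: *cacna1g*, which encodes a T-type calcium channel (3896 ± 483 against 2923 ± 154). The abundant exchanger gene *slc8a1a* stood at 10900 ± 519 against 10510 ± 845 and the ryanodine receptor gene *ryr2b* at 10070 ± 902 against 10040 ± 503. This list passed, upward, without mutant replicate 1 (0.0293) or WT replicate 1 (0.0238), and with no value filter (0.0473). The 23 cardiac transcription factor genes had a median of 0.03 (adjusted p = 0.162; 0.00789 without WT replicate 1), with *gata5* at 2378 ± 68.9 against 2131 ± 158 and *tbx20* at 2215 ± 73.9 against 2196 ± 271. The 13 natriuretic peptide and load response genes were higher as a group, with a median of 0.10 (adjusted p = 0.019; adjusted p = 0.501 with an estimated correlation) and no member past the test. The skeletal-type actin gene *acta1b* stood at 9534 ± 909 against 7702 ± 755. That call ended without mutant replicate 3 (0.112), WT replicate 2 (0.173) or WT replicate 3 (0.208). The list's mean difference of 0.10 went to 0.06 without WT replicate 3 and to 0.17 without WT replicate 1 (adjusted p = 4e-05).

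Among signalling pathways, the 27 YAP/TAZ target genes did not pass as a list. Their median log2 change was 0.05, their mean was −0.01, and the camera adjusted p was 0.244. None passed alone: *cyr61* stood at 395 ± 64.1 against 285 ± 20.1, *ctgfb* at 79.7 ± 25.4 against 51.0 ± 5.29 and *ankrd1a* at 21.0 ± 13.9 against 41.0 ± 9.16 (3 genes chosen after their values were seen). The most abundant members were *amotl2a* at 1669 ± 151 against 1692 ± 76.2 and *crim1* at 998 ± 77 against 939 ± 69.9. The 30 Hippo core genes had a median of 0.05 (adjusted p = 0.0491; adjusted p = 0.545 with an estimated correlation). Their most abundant members were the atypical cadherin gene *fat1a* at 7102 ± 358 against 7122 ± 552 and CABZ01069287.1, which the gene name table calls *FAT4*, at 1498 ± 81.5 against 1262 ± 54.4. The call ended without mutant replicate 1 (0.117), mutant replicate 2 (0.17) or WT replicate 2 (0.792), and also under 5 other settings of the value filter, the scaling and the library weights (adjusted p between 0.0518 and 0.109). WT replicate 2 carried nearly all of the list's mean difference of 0.07, which was 0.0043 without it, and 0.11 without WT replicate 3 (adjusted p = 0.01).

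The 25 neuregulin and ErbB genes, a pathway needed for trabeculation, had a median log2 change of 0.11 (camera adjusted p = 0.0117; adjusted p = 0.446 with an estimated correlation, and 0.0568 without WT replicate 1, where the mean difference went from 0.11 to 0.06). None passed alone, and the feedback phosphatase gene *dusp6* stood at 1815 ± 139 against 1606 ± 147. The 36 Notch genes had a median of 0.06 (adjusted p = 0.137; 0.0246 without WT replicate 1), and the ligand gene *jag2b* rose when adjusted over the list alone (872 ± 44.3 against 671 ± 21.9). *notch2* stood at 1189 ± 115 against 1105 ± 63.5. The 34 BMP and TGF-beta genes had a median of 0.04 and a mean of −0.07 (adjusted p = 0.162, tested upward; 0.0167 without WT replicate 1, and 0.00969 among genes with a value of at least 50). *BMP10* fell over all genes tested, and *smad7*, an inhibitor of the pathway, rose when adjusted over the list alone (325 ± 18.3 against 240 ± 22.7). The follistatin-like gene *fstl1b* stood at 4930 ± 310 against 4843 ± 393. The 20 Wnt genes had a median of 0.11 (adjusted p = 0.244). Adjusted over that list alone, the ligand gene *wnt2bb* rose (354 ± 42.6 against 223 ± 15.5) and the secreted antagonist gene *sfrp5* fell (176 ± 14.4 against 276 ± 9.16), while *fzd7a* and *vangl2* did not pass (920 against 874, and 781 against 890).

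Neither of the cell-shape lists passed. The 42 junction and adhesion genes had a median log2 change of 0.00 and a mean of −0.02 (camera adjusted p = 0.71, tested upward), with the cadherin gene *cdh2* at 4654 ± 72.3 against 4665 ± 541 and *ctnnb1* at 3452 ± 65.7 against 3210 ± 81.6. The 37 genes of the actin cytoskeleton and Srf targets had a median of 0.01 (adjusted p = 0.244; 0.0442 without mutant replicate 2). Adjusted over this list alone, the non-muscle myosin heavy chain gene *myh10* fell (6147 ± 372 against 8313 ± 319, a log2 change of −0.44, SE 0.0856) and the myosin light chain gene *myl9a* rose (272 ± 12.7 against 203 ± 11). The actin genes *actb1* and *actb2* stood at 11390 ± 951 against 11160 ± 820 and at 14960 ± 868 against 15150 ± 1156.

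Mitochondrially encoded genes, nuclear genes of oxidative phosphorylation and glycolysis genes were each lower in mutant hearts by camera with the preset correlation. All 13 mitochondrially encoded genes had a log2 change below 0 and 12 had every mutant value under every WT value; the median was −0.24 (camera adjusted p = 5.71e-10; adjusted p = 0.455 with an estimated correlation), and 5 fell when adjusted over the list alone. Among those 5, *mt-nd4* stood at 9298 ± 729 against 11340 ± 1005 and *mt-atp6* at 14220 ± 812 against 17220 ± 1474. The members' estimated correlation was 0.668, so they are not 13 separate signals. The list's mean deviations were 0.27, 0.07 and 0.01 in WT and −0.14, −0.05 and −0.16 in mutant replicates 1 to 3. Its mean difference went from −0.23 to −0.16 without WT replicate 1 (camera adjusted p = 9.22e-06). Of the 89 nuclear genes of oxidative phosphorylation, 81 had a change below 0, with a median of −0.12 (adjusted p = 2.06e-08; adjusted p = 0.455 with an estimated correlation). None passed alone, and the ATP synthase gene *atp5a1* stood at 5227 ± 173 against 5915 ± 246. WT replicate 1 stood apart, with a mean deviation of 0.17 against 0.02 and 0.00 in WT replicates 2 and 3, and mutant replicate 1 was at 0.01. Without WT replicate 1 the list's mean difference went from −0.13 to −0.08 and its adjusted p was 0.00789. The 31 glycolysis genes had a median of −0.14 (adjusted p = 0.000439; adjusted p = 0.455 with an estimated correlation, and 0.0851 without WT replicate 1, where the mean difference went from −0.12 to −0.07). Adjusted over the list alone, *eno3* (2698 ± 101 against 3518 ± 9.61), the muscle enolase gene, and *pfkpa* (749 ± 8.02 against 927 ± 45.4), which encodes a phosphofructokinase, fell; *gapdh* stood at 9102 ± 541 against 8511 ± 963. The 31 genes of fatty acid oxidation and mitochondrial biogenesis had a median of −0.05 (adjusted p = 0.342), with *acsl1b* at 2083 ± 170 against 2265 ± 188. The share of all values on the mitochondrial chromosome was 7.42%, 8.14% and 6.69% in mutant replicates 1 to 3 and 10.2%, 7.46% and 7.57% in WT replicates 1 to 3.

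The list of ribosomal protein genes was lower by a median log2 change of −0.08 over 92 genes (camera adjusted p = 1.5e-06; adjusted p = 0.501 with an estimated correlation). It takes in 7 genes that do not encode ribosomal proteins, such as the kinase gene *rps6ka5*, and had an adjusted p of 8.3e-08 without them. The list's mean deviation was −0.10 in mutant replicate 2, against 0.01 and −0.02 in mutant replicates 1 and 3, and without mutant replicate 2 its mean difference went from −0.07 to −0.04 (adjusted p = 0.0288). *rpl4* stood at 8273 ± 97.8 against 9012 ± 676 and *rps2* at 9111 ± 267 against 9564 ± 120. The 50 cell cycle genes had a median of −0.09 (adjusted p = 0.00451; adjusted p = 0.455 with an estimated correlation, and 0.162 without WT replicate 3, where the mean difference went from −0.10 to −0.06) and none passed alone. The proliferation marker *mki67* stood at 1912 ± 12.5 against 2092 ± 174 and the kinetochore motor gene *cenpe* at 1594 ± 81.9 against 1769 ± 119.

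Immediate early genes, which respond within minutes to growth factors, stress and handling, were higher in mutant hearts. The 23 measured members had a median log2 change of 0.48 (camera adjusted p = 3.35e-08; adjusted p = 0.455 with an estimated correlation), and 8 rose when adjusted over the list alone, among them *egr1* (727 ± 248 against 474 ± 48.6), *fosl2* (279 ± 66.2 against 184 ± 17.5) and *socs3a* (364 ± 97.5 against 207 ± 34.3), which stands in the table as a pair of near-identical rows. Mutant replicate 1 stood far above the others, with a mean deviation of 0.82 on the log2 scale against 0.01 and −0.19 in mutant replicates 2 and 3. WT replicates 1 to 3 stood at −0.11, −0.30 and −0.24, so mutant replicate 3 lay below WT replicate 1. Without mutant replicate 1 the list's mean difference went from 0.43 to 0.13 and the adjusted p was 0.0192. The 18 p53 target and cell death genes (median −0.02, mean 0.00, adjusted p = 0.821, tested downward), the 32 protein folding genes (median 0.02, adjusted p = 0.52) and the 23 circadian clock genes (median 0.06, adjusted p = 0.0935) did not pass. Without mutant replicate 2 or WT replicate 3 the folding list passed, upward (0.039 and 0.0278), as did the clock list without mutant replicate 3 or WT replicate 1 (0.048 and 0.0174) or with no value filter (0.0372).

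**Figure D3:**
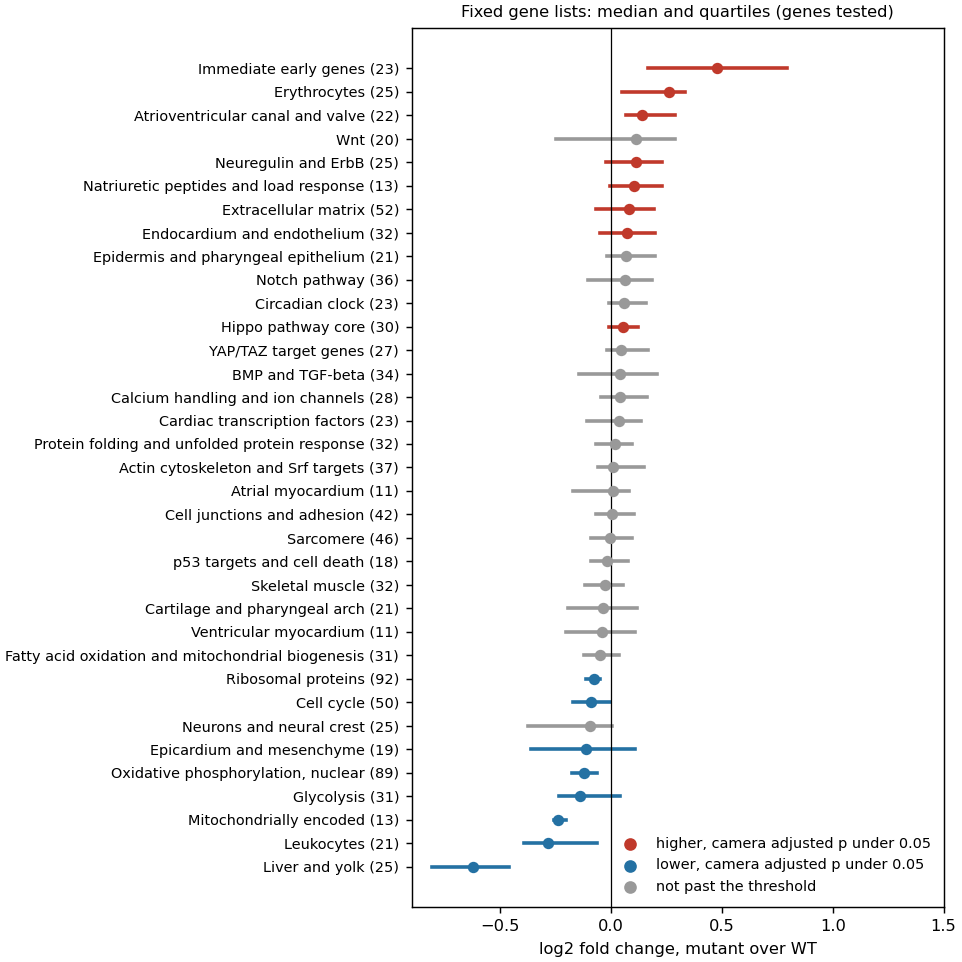
Median log2 change between mutant and WT hearts (point) and the lower to upper quartile (bar) of the tested members of each of the 35 lists, with the number tested in brackets; red and blue lists were higher or lower by camera with a preset correlation. Medians run from −0.62 for the liver and yolk list to 0.48 for the immediate early genes.

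Markers of blood and of tissues next to the heart also differed between libraries. The 25 erythrocyte genes were higher, with a median log2 change of 0.26 (camera adjusted p = 1.38e-06; adjusted p = 0.455 with an estimated correlation), and none passed alone. The embryonic globin gene *hbae3* stood at 44920 ± 11280 against 35260 ± 1746 and *hbbe1.1* at 53190 ± 15530 against 45930 ± 3870. The list's mean deviations were 0.32, −0.20 and 0.16 in mutant replicates 1 to 3, against 0.01, −0.10 and −0.19 in WT replicates 1 to 3. Its mean difference of 0.19 went to 0.08 without mutant replicate 1 (adjusted p = 0.0293) and to 0.34 without mutant replicate 2 (1.73e-16). The 21 leukocyte genes were lower, with a median of −0.29 (adjusted p = 0.0117; adjusted p = 0.455 with an estimated correlation); that call ended without mutant replicate 3 (0.0808) or WT replicate 1 (0.171, where the mean difference went from −0.21 to −0.13), and *lyz* stood at 146 ± 60.5 against 202 ± 84.0.

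The liver and yolk list had the lowest median of the 35 lists. All 25 measured genes had a log2 change below 0, with a median of −0.62 (camera adjusted p = 2.46e-21; adjusted p = 0.446 with an estimated correlation), and 18 fell when adjusted over the list alone. The fibrinogen gene *fgb* stood at 161 ± 33.8 against 271 ± 16.6, and the apolipoprotein genes *apobb.1* and *apoa1b* at 7096 ± 2052 against 9728 ± 2550 and at 2349 ± 628 against 3924 ± 1246. The list's mean deviations were −0.43, −0.58 and 0.08 in mutant replicates 1 to 3 and 0.18, 0.59 and 0.15 in WT replicates 1 to 3.

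The lists of other surrounding tissues did not pass. The 32 skeletal muscle genes had a median log2 change of −0.03 (camera adjusted p = 0.71), the 21 epidermal and pharyngeal epithelial genes 0.07 (adjusted p = 0.0697), the 21 cartilage genes −0.04 (adjusted p = 0.821) and the 25 neuronal and neural crest genes −0.10 (adjusted p = 0.0636). Adjusted over the muscle list alone, *mybpc1* rose (280 ± 16.9 against 176 ± 46.2) and *mybphb*, shared with the atrial list, fell. The keratin gene *krt4* stood at 36860 ± 4131 against 36320 ± 7951, the fast myosin gene *myhz1.1* at 12130 ± 1967 against 12840 ± 4860 and the collagen gene *col2a1a* at 3974 ± 746 against 4177 ± 1424. Single libraries decided some of these results: the muscle list passed upward without WT replicate 2 (9.82e-07) and downward without WT replicate 3 (0.00154), the epidermal list upward without mutant replicate 2 (8.13e-05) or WT replicate 2 (9.82e-07), and the cartilage list upward without WT replicate 1 (0.00789). The epidermal list also passed with no value filter (0.0462) and with library weights (0.0161). The neuronal list passed downward without mutant replicate 2 (0.0288), mutant replicate 3 (0.048) or WT replicate 1 (0.0176).

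**Figure D4:**
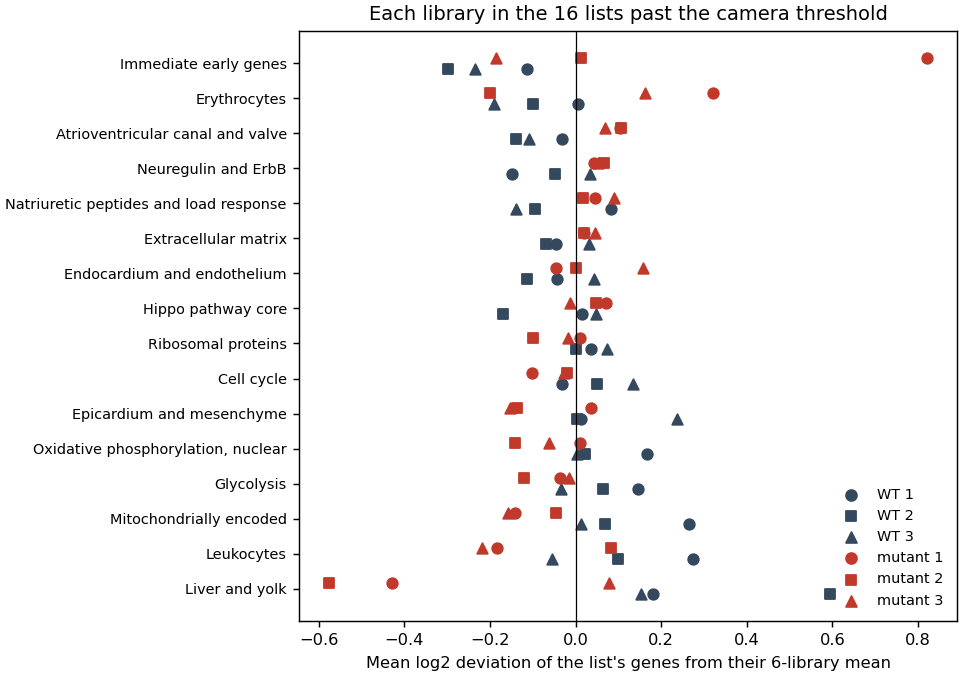
Mean log2 deviation of each list's genes from their mean over the 6 libraries, for the 16 lists past the camera threshold, in 3 WT libraries (dark) and 3 mutant libraries (red). In the immediate early list mutant replicate 1 stands apart at 0.82, and in the liver and yolk list mutant replicate 3 (0.08) lies close to WT replicates 1 and 3 (0.18 and 0.15).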

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

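Robust variance moderation, precision weights, rescaling without the 20 most abundant features, the ribosomal list without kinases and leaving *wwtr1* out of the chromosome count were chosen after seeing the data. The fall of *wwtr1* passed under every alternative run, with log2 changes of −1.57 to −1.86 when 1 library was left out. Against 2 genes higher and 5 lower, robust moderation gave 9 and 13. A minimum log2 change of 1 left 1 higher gene and an adjusted p under 0.01 left 2 lower genes, in each because the rule is stricter. Leaving out chromosome 22 left 1 higher and 3 lower genes. That setting removes *wwtr1* and *alpi.1* themselves. The other lower gene lost is *abraa*, the call nearest the threshold (adjusted p = 0.0469 in the main limma test). With 1 library left out, 2 to 32 genes were higher and 3 to 11 lower, and the 32 higher without WT replicate 2 include *he1a*, *he1b* and *ctslb*, which were highest in that replicate among WT hearts; the cause for the others was not tested. Camera with an estimated correlation and fry each called 0 of the 35 lists, against 16. The skeletal muscle list turned from a downward to an upward direction without WT replicate 2 (adjusted p = 9.82e-07, range 9.82e-07 to 0.519 over left-out libraries). The cartilage list did so without WT replicate 1 (0.00789, range 0.00789 to 0.653). Each was the WT library highest in that list. The muscle deviation was 0.39 in WT replicate 2, against −0.16 and −0.20 in WT replicates 1 and 3. The cartilage deviation was 0.42 in WT replicate 1, against −0.17 and −0.10 in WT replicates 2 and 3. Why these libraries stood apart was not tested. With *wwtr1* left out, 1 called gene lay on chromosome 22 in place of 2 (Fisher's exact test, p = 0.199). *abraa* also missed the threshold with no value filter (0.0646), with a minimum value of 50 (0.0679) and with quantile normalisation (0.0826). The effect of depth was not tested. In the simulation at this replicate number, 50% of 1.5-fold and 92% of 2-fold changes were recovered among genes with a mean of at least 50. The simulated spread followed the mean alone, so these shares do not cover lower genes or genes of wider spread.

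With the replicate number as a block, 8 genes were higher, *he1a*, *he1b* and *ctslb* among them, and 7 lower, and 14 lists passed in place of 16: the matrix and Hippo core lists missed the threshold (adjusted p = 0.0586 and 0.0572). No pairing by number was seen over all tested genes, where the deviations of same-numbered libraries correlated at 0.02, −0.02 and −0.02. Mutant replicates 2 and 3 each correlated best with a WT library of another number. With 3 libraries per group these correlations cannot exclude a pairing. *he1a*, *he1b* and *ctslb* were highest in replicate 2 of both genotypes. The 2 planned count models, on raw counts or recovered reads, were not run, since the table holds rounded scaled values.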

Other observations

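The KEGG terms were chosen after seeing the data, as were the tests of the other splits, of chromosome 22 and of neighbouring tissues; the tests of the valve list were set beforehand, except the permutation tests with 1 library left out. Among 141 KEGG terms of 10 to 291 tested genes, taken from the table's own annotation, camera with the preset correlation placed 4 higher and 26 lower in mutant hearts, and 0 held by camera with an estimated correlation (lowest adjusted p = 0.462, with 12 terms at an unadjusted p under 0.05). The lower term with the smallest p was Ribosome, with 125 genes and a median log2 change of −0.09 (adjusted p = 3.71e-08, and 0.489 with an estimated correlation). Pyruvate metabolism (38 genes) had a median log2 change of −0.17 (adjusted p = 1.47e-05; adjusted p = 0.462 with an estimated correlation) and the folate one-carbon pool (18 genes) also −0.17 (adjusted p = 0.000235, and 0.462 with an estimated correlation). The term with the smallest adjusted p among the higher ones was TGF-beta signalling, with 85 genes and a median of 0.06 (adjusted p = 0.000988, and 0.489 with an estimated correlation).

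Further genes just missed the threshold, with adjusted p between 0.05 and 0.1, so that 9 genes were higher and 11 lower at an adjusted p under 0.1. Among them, chosen after their values were seen, the myoglobin gene *mb*, the ephrin gene *efna5a* and the endothelin gene *edn2* had log2 changes of 0.55, −0.76 and 0.84. Transcripts of the hatching enzymes *he1a* and *he1b* and of the cathepsin gene *ctslb*, known from the hatching gland and also chosen after their values were seen, differed within WT hearts, where replicate 2 stood 2.78 to 5.99 times above the next replicate. They are among the genes called higher without WT replicate 2. *he1b* stood at 150, 455 and 85 in WT replicates 1 to 3 and at 462, 673 and 337 in mutant replicates 1 to 3, and *ctslb* (ENSDARG00000074306) at 223, 1090 and 177 against 600, 1421 and 650; the reads of *he1a* and *he1b*, which overlap, may be shared. Thyroglobulin, *tg*, stood at 299, 348 and 2438 in mutant and 1727, 1002 and 1017 in WT replicates 1 to 3.

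The 3 against 3 libraries make only 10 splits, too few for a share under 0.05. The real split gave 7 genes and the highest of the other splits gave 8, so 2 of the 10 splits gave as many as the real one. The 8 genes of that other split, mutant replicates 1 and 3 with WT replicate 2 against the rest, are all U5 and U6 small nuclear RNA genes. They moved together, with log2 changes between the sides of 0.76 to 0.83, and are not 8 separate signals. All small nuclear RNA took 1.57%, 1.2% and 1.49% of the total in mutant replicates 1 to 3. In WT replicates 1 to 3 it took 1.18%, 1.32% and 1.25%.

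Genes near *wwtr1* on chromosome 22 differed between genotypes more often than genes elsewhere. The mean squared moderated t of the 112 genes within 10 Mb was 3.25 against 1.36 elsewhere, at percentile 100 of 15514 runs of as many neighbouring genes on other chromosomes, and 19 of the 112 against 6.49% elsewhere had an unadjusted p under 0.05 (Fisher's exact test, p = 0.000127). Liver transcripts in this window do not account for it: without *fetub*, *kng1* and *cp* the percentile was still 100, and without *alpi.1* too it was 99.2. A candidate explanation is a haplotype that travels with the mutant allele, so that *alpi.1*, *tm4sf18* and *commd2* may differ between siblings by linked sequence variation. An effect of the genotype on its neighbours was not tested and stays open.

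Liver and yolk transcripts differed between libraries, and the list's mean deviation in mutant replicate 3 (0.08) lay close to those in WT replicates 1 and 3 (0.18 and 0.15). Carry-over of every surrounding tissue by about as much as liver is argued against by the pooled muscle, cartilage and epidermis genes. Their median log2 change was −0.01 (SD over genes 0.257, 74 genes) against −0.62. A group median cannot exclude uneven carry-over into single libraries. WT replicate 2 had the highest mean deviation of the muscle list (0.39) and the epidermal list (0.23), as of the liver list (0.595). Its cartilage deviation was −0.17, where WT replicate 1 was highest (0.42). Liver and yolk RNA from 1 source stays open. The members' estimated correlation of 0.501 goes with it, but does not tell it apart from a shared change in expression. The mitochondrially encoded list had 0.668. The tests of a fixed ratio disagree. The chi-square p was 0.0302 for the spread of the liver and yolk members' changes. The simulated p was 0.164 (power 33.2%) once each library's list mean was taken off. With apolipoprotein genes and the others taken as 2 sources, the same tests disagree for the apolipoprotein genes only. For these genes the chi-square p was 0.621. Their simulated p, with each library's set mean taken off, was 0.0151 (power 82.5%). For the other genes the chi-square p was 0.142 and the simulated p was 0.371 (power 18.9%). These tests therefore do not decide whether there were 2 sources. An effect of the genotype on liver or yolk was not tested.

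The rise of atrioventricular canal and valve genes did not rest on 1 library, since the highest adjusted p with 1 library left out was 0.000222 by camera with the preset correlation. With all libraries it was lost with an estimated correlation (adjusted p = 0.446) and by fry (adjusted p = 0.381). A larger endocardial share in mutant samples stays open: the mean log2 change was 0.19 over the 22 valve genes and 0.08 over the 32 endocardial genes, and a 2-sided permutation test over genes, which are not independent replicates, gave p = 0.105 for the difference. The endocardial mean was 0.01 without mutant replicate 3 and 0.04 without WT replicate 2, with the valve mean at 0.20 and 0.16 (permutation p = 0.0118 and 0.0778). More endocardial cells in the pools and higher expression per cell are therefore not separated here.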
